A study of Trichoderma reesei with 6 samples.

How the data were processed

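RNA from hyphae of Trichoderma reesei strain HJ48 was sequenced in 3 libraries from glucose and 3 from xylose fermentation. Per the labels' protocols, RNA was taken up in Trizol and libraries were made with an NEBNext Ultra DNA library kit for Illumina sequencing. The deposited file is 1 table of FPKM (fragments per kilobase of gene model, scaled to the library total) for 9129 gene models in the 6 libraries, made by the authors, with 1 column per library. Bowtie2 2.2.3, TopHat2 2.0.12 and HTSeq 0.6.1 are named in the submitters' processing notes, with no role given. The genome build and annotation are not given in the sources used here. FPKM divides by the library total, so a change in a few abundant genes moves the value of every other gene. Whether counting used strand is not given in the sources used here, so reads of overlapping or antisense genes cannot be told apart, and reads of near-identical genes may have been shared or dropped.

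Columns were matched to samples by the descriptions in the labels. The model names have the form of prediction series of the genome project. None of the 9129 names matched an identifier among the 9116 genes of the reference table used here (assembly v2.0 of strain QM6a), so 0 models could be given a symbol or a product. The gene lists fixed by product before the data were examined could therefore not be filled, and the tests planned on them were not run. Scaffold numbers were read from the names. Over 45 scaffolds, the number of models per scaffold was compared with the number of genes in each block of ascending positions of the reference table, which was equal for 33 scaffolds and differed by at most 5 genes in the others. That table was used for nothing else.

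Depth was worked out from the steps between low FPKM values. For counted reads, FPKM is the read number times a constant divided by gene length and library total. The most frequent ratio of low values between libraries gave relative totals. Candidate totals had to make most of the lengths worked out at this step, and all 6 totals, whole numbers. The first to do so (largest deviation of a total 0.0036, tolerance 0.05) were taken as the implied library totals. Whole reads and a whole length from 60 to 20000 nt could be solved for 9008 models, 99.98% of those above 0, within a tolerance of 1e-05 reads plus a relative 3e-09. The solved reads summed to 99.1% to 99.3% of each implied total. A length is the smallest solution and can be too short where all reads share a factor. On 3000 simulated models the totals of all 6 libraries came back exact. So did the reads of 99.3% of the simulated models with reads in more than 1 library. Implied totals of 8887469 to 11449774 reads limit precision mainly for models near 1 FPKM, and reads without molecular identifiers are not independent molecules.

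FPKM values were used as deposited for the main test. Models with a mean of at least 1 FPKM over the 6 libraries were tested, 7766 in all. log2(FPKM + 1) was fitted by carbon source with limma 3.58.1 in R 4.3.3 (lmFit, eBayes with a trend), two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. Fold changes are on the log2(FPKM + 1) scale, xylose minus glucose. In simulated reads, 81 of 100 models changed 2-fold and 99 of 100 changed 4-fold were recovered, and 14 of 7545 unchanged models were called. The simulation gave every model the same dispersion, 0.0242, a median within groups of these libraries, and no common shift. The real groups differed in spread (median SD of 0.181 log2 units in glucose and 0.311 in xylose) and most models shifted. These rates therefore do not carry over to the real contrast. Per-library measures were compared by two-sided exact permutation tests (SciPy 1.17.1, Python 3.11.15). Scaffolds with at least 20 tested models were compared with all other models by limma's camera with a preset correlation of 0.01 and, separately, an estimated one. On shuffled scaffolds camera called 0 of 39, and a group of 300 models shifted by 1 log2 unit was recovered (adjusted p = 1.65e-05). A shift of 0.5, tried first, was not (adjusted p = 0.166). Shuffling removes the correlation between models of a scaffold, so the simulated data do not test false calls that come from it. The scaffold groups, the classes of level and the set of switched models were chosen after the table was seen.

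The rule for named models was fixed before the data were examined. With no names to match, it gives at most 2 models in each direction, those with the largest log2 fold change past the threshold, with a mean of at least 5 FPKM and groups that do not overlap. Settings also tried were pseudocounts of 0.1 and 5, no filter and a filter at 5 FPKM. Other scalings were the median of ratios, quantile normalization and rescaling to TPM. The fit was varied with a replicate block, array weights, and eBayes made robust and without a trend. A threshold of 0.01, limma's treat against a 1.5-fold change, and leaving out each library were tried too. Added after the table was seen were voom on the recovered reads and scaling on the reads outside the 100 most abundant glucose models. The edgeR quasi-likelihood test was planned only if the table held counts too, and it was not run, because the deposited unit is FPKM.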

Results

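Gene expression was measured by RNA sequencing in hyphae of Trichoderma reesei, a filamentous fungus best known as an industrial producer of cellulases. The labels give 1 strain, HJ48, and 2 conditions, anaerobic fermentation of glucose and anaerobic fermentation of xylose, both at an age of 4 days. The series title speaks of strains in the plural, while all 6 samples carry the same strain label. Each condition had 3 libraries. The series title names the question, the molecular basis for fermenting the hexose glucose and the pentose xylose. Nothing in the labels says whether the 3 libraries of a condition came from separate cultures, so the p-values measure the spread between these samples, which may be technical. The deposited table lists FPKM for 9129 gene models. Library totals implied by the steps between low FPKM values were 8887469, 10102493 and 9803227 reads for glucose replicates 1, 2 and 3. They were 10739898, 11435911 and 11449774 reads for xylose replicates 1, 2 and 3. The table names gene models by prediction series and does not pair them with gene symbols or products, so no gene function is given here. Gene groups were formed by level, by carbon source and by the scaffold number in the model names.

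Libraries of the same carbon source were alike and the 2 carbon sources stood far apart. Pearson correlations across genes of log2(FPKM + 1), over 7766 tested models, ran from 0.989 to 0.992 within glucose, from 0.96 to 0.977 within xylose and from 0.773 to 0.847 between the groups. These are correlations across genes, which are not independent replicates. The first principal component held 92.2% of the variance and parted glucose from xylose. The median SD of a model between libraries was 0.181 log2 units in glucose and 0.311 in xylose. Among the xylose libraries, replicate 1 lay farthest from glucose and replicate 3 nearest.

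The glucose libraries were dominated by few models, and the xylose libraries spread their reads over many more. The 10 most abundant models of each library held 27.97% ± 1.19 of reads in glucose and 16.5% ± 1.65 in xylose (SD, n = 3). A share of 0.5 of the reads came from 58 ± 4 models in glucose and from 132.7 ± 34.6 models in xylose. A level of at least 1 FPKM was reached by 6380 ± 89.3 models in glucose and 7851 ± 121 in xylose. Models listed at 0 numbered 733.7 ± 32.7 in glucose and 335.7 ± 33.3 in xylose. The median FPKM of all models was 3.627 ± 0.27 in glucose and 11.33 ± 2.65 in xylose. In each of these 5 measures the groups did not overlap, and the two-sided exact permutation test gave p = 0.1, the smallest that 3 libraries against 3 allow. The implied library totals also did not overlap, and each xylose library was deeper than each glucose library.

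**Figure D1:**
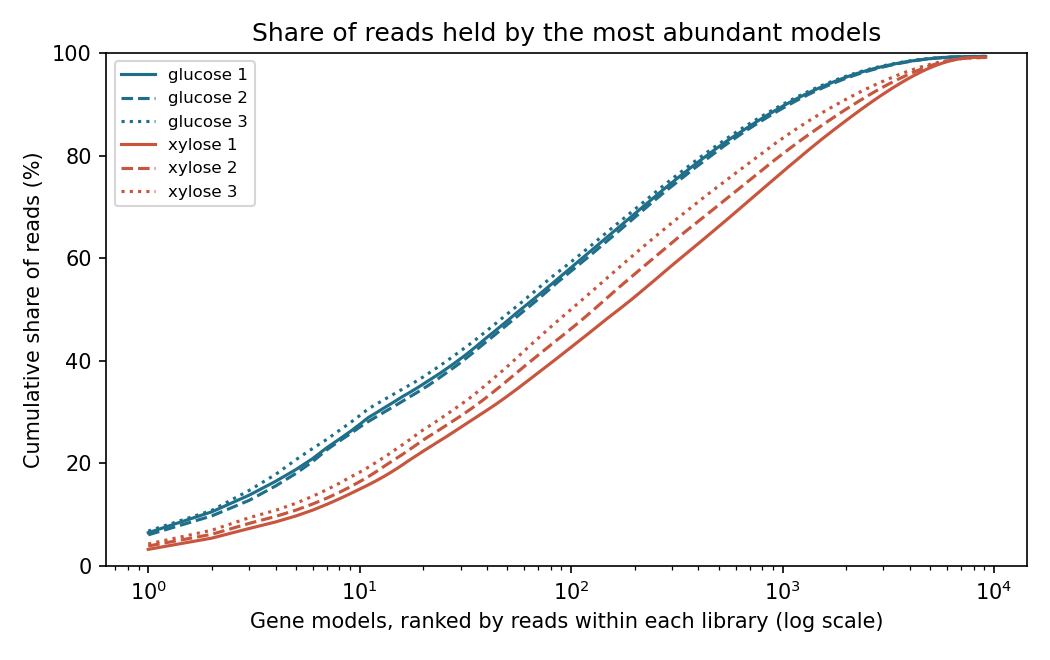
Cumulative share of reads (vertical axis, percent) against gene models ranked by reads within each library (horizontal axis, log scale), with 1 line per library. The 3 glucose lines lie above the 3 xylose lines over the first 100 models, where the 100 most abundant models held 58.33% ± 0.907 of reads in glucose and 46.27% ± 3.7 in xylose (SD, n = 3).

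The models that dominated the glucose libraries took a smaller share of reads on xylose, and the direction of the 100 leading xylose models depended on the scaling. Of the 100 models with the largest share of reads in glucose, 62 fell, 14 rose and 24 did not pass the test. Together they held 58.2% ± 0.9 of reads in glucose and 39.7% ± 3.5 in xylose (SD, n = 3). The single model with the highest FPKM in glucose, with an implied length of 267 nt, had 64056 ± 20078 FPKM in glucose and 6531 ± 1176 in xylose, a log2 fold change of -3.27 (SE 0.22, limma adjusted p = 8.91e-07). The model with the highest FPKM in xylose rose from 3789 ± 331 to 27782 ± 2365 FPKM, a log2 fold change of 2.87 (SE 0.14, limma adjusted p = 1.44e-07). These single models were ranked by FPKM, which divides by length, and not by their share of reads. Of the 100 most abundant xylose models, 48 rose, 29 fell and 23 did not pass, while together they held 53.1% ± 1.3 of reads in glucose and 46.1% ± 3.7 in xylose. Both lists were chosen on these libraries, so their counts are not independent evidence of direction. With scaling by the median of ratios, 90 of the glucose list fell and 1 rose, and the direction of the xylose list turned, with 57 lower and 19 higher. The 2 lists shared 66 of 100 models, and 7 of the 10 most abundant.

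Most tested models rose on xylose relative to the library total. Of 7766 models with a mean of at least 1 FPKM, 5035 (64.8%) were higher in xylose, 1095 (14.1%) were lower and 1636 were not called, by limma on log2(FPKM + 1) with a Benjamini-Hochberg adjusted p under 0.05. A change of at least 2-fold on that scale was seen in 4702 of the called models, 4109 of them higher and 593 lower. On FPKM as deposited, groups did not overlap in 81.4% of tested models, where exchangeable libraries would give 10% for a single model. All models share the same 6 libraries and the common shift given next, which can part the groups by itself. The 81.4% is therefore not a share of models that changed independently. The median tested model was higher in xylose by a log2 fold change of 1.10, and by 0.81 to 1.41 over the 9 pairings of a xylose with a glucose library. The split of calls rests on the scaling. Scaling by the median of ratios across models, which sets aside that common shift, left a median of 0.10 and gave 2980 higher and 2721 lower, so 52.3% of calls were higher against 82.1% with FPKM as deposited. Both scalings called 4340 models in common, 4075 of them in the same direction.

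The rise was largest in models under 10 FPKM, and the median model above 500 FPKM was lower in xylose. Models with a mean of 1 to 5 FPKM had a median log2 fold change of 1.30, with 1574 of 2191 higher and 153 lower. Models of 5 to 10 FPKM had the largest median, 1.5, with 1010 of 1352 higher and 104 lower. Models of 10 to 50 FPKM had a median of 1.07, with 1698 of 2620 higher and 324 lower. The median was 0.61 in the class of 50 to 100 FPKM, with 361 higher and 155 lower of 645. In the class of 100 to 500 FPKM the median was 0.17, with 315 higher and 246 lower of 716. Above 500 FPKM the median was -0.25, with 77 higher and 113 lower of 242 models. With scaling by the median of ratios the 6 medians, from the lowest class to the highest, became 0.55, 0.48, -0.07, -0.58, -1.04 and -1.46. The sign turned in the 3 classes from 10 to 500 FPKM, and the class of 5 to 10 FPKM no longer had the largest median. The pseudocount of 1 understates the fold change of low models.

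**Figure D2:**
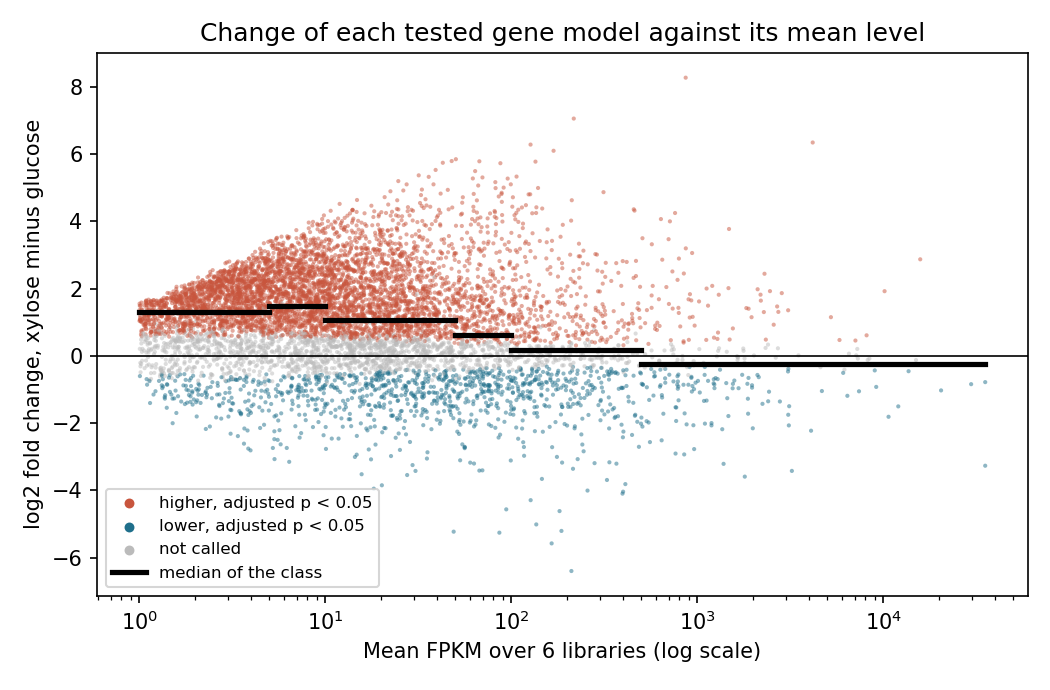
Log2 fold change, xylose minus glucose (vertical axis), against mean FPKM over the 6 libraries (horizontal axis, log scale), with 1 point per tested model coloured by call and a black bar at the median of each class of mean FPKM. The medians lie at 1.30 in the 1 to 5 FPKM class and at -0.25 above 500 FPKM on FPKM as deposited, and at 0.55 and -1.46 with the median of ratios.

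A set of models went from near silence on glucose to clear expression on xylose, and its size depended on the scaling. There were 72 models under 1 FPKM in every glucose library and at least 10 FPKM in every xylose library. Their median level was 0.445 FPKM in glucose and 19.1 in xylose. The reverse set, under 1 FPKM in every xylose library and at least 10 in every glucose library, held 0 models. With levels scaled by the median of ratios, the same limits gave 14 models in the first set and 6 in the reverse set. All 72 models found on FPKM as deposited still passed the limma test with that scaling. The smaller set thus reflects the fixed limits of 1 and 10 FPKM and not a loss of calls. A log2 fold change of at least 4 in size was called for 138 models that rose and 12 that fell. With the median of ratios these numbers turned to 28 and 45, and with quantile normalization they were 37 and 29. They were 568 and 23 with a pseudocount of 0.1, 33 and 6 with a pseudocount of 5, and 665 and 24 with voom on recovered reads. The number of strong changes thus moved with the pseudocount, which voom replaces by a small offset on reads, while the excess of rises turned with the median of ratios and shrank with quantile normalization.

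The 2 models with the largest rise were estExt_GeneWisePlus.C_11554 and estExt_fgenesh5_pg.C_290049, on scaffolds 1 and 29 by their names. estExt_GeneWisePlus.C_11554, with an implied length of 2425 nt, had 4.14 ± 0.126 FPKM in glucose and 1726 ± 860 in xylose (SD, n = 3), a 417-fold ratio of means. It had 289 reads over the 3 glucose libraries and 141959 over the 3 xylose libraries. Its log2 fold change was 8.28 (SE 0.28, limma adjusted p = 4.69e-08). estExt_fgenesh5_pg.C_290049, with an implied length of 682 nt, had 2.35 ± 1.05 FPKM in glucose and 430.5 ± 39.4 in xylose, a 183-fold ratio. Its log2 fold change was 7.06 (SE 0.24, limma adjusted p = 4.69e-08), from 47 reads in glucose and 9875 in xylose. With the median of ratios the log2 fold changes of the 2 models were smaller, 7.16 for estExt_GeneWisePlus.C_11554 and 6.02 for estExt_fgenesh5_pg.C_290049.

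The 2 models with the largest fall were fgenesh5_pg.C_scaffold_29000077 and estExt_GeneWisePlus.C_290128, both on scaffold 29. fgenesh5_pg.C_scaffold_29000077, with an implied length of 1500 nt, had 416.4 ± 159.8 FPKM in glucose and 4.02 ± 1.94 in xylose, 104-fold lower by the ratio of means. Its log2 fold change was -6.40 (SE 0.33, limma adjusted p = 2.12e-07). estExt_GeneWisePlus.C_290128, with an implied length of 1767 nt, had 323.5 ± 118.9 FPKM in glucose and 5.68 ± 1.67 in xylose, 56.9-fold lower. Its log2 fold change was -5.58 (SE 0.27, limma adjusted p = 1.56e-07). With the median of ratios both falls were larger, with log2 fold changes of -7.43 for fgenesh5_pg.C_scaffold_29000077 and -6.68 for estExt_GeneWisePlus.C_290128.

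**Figure D3:**
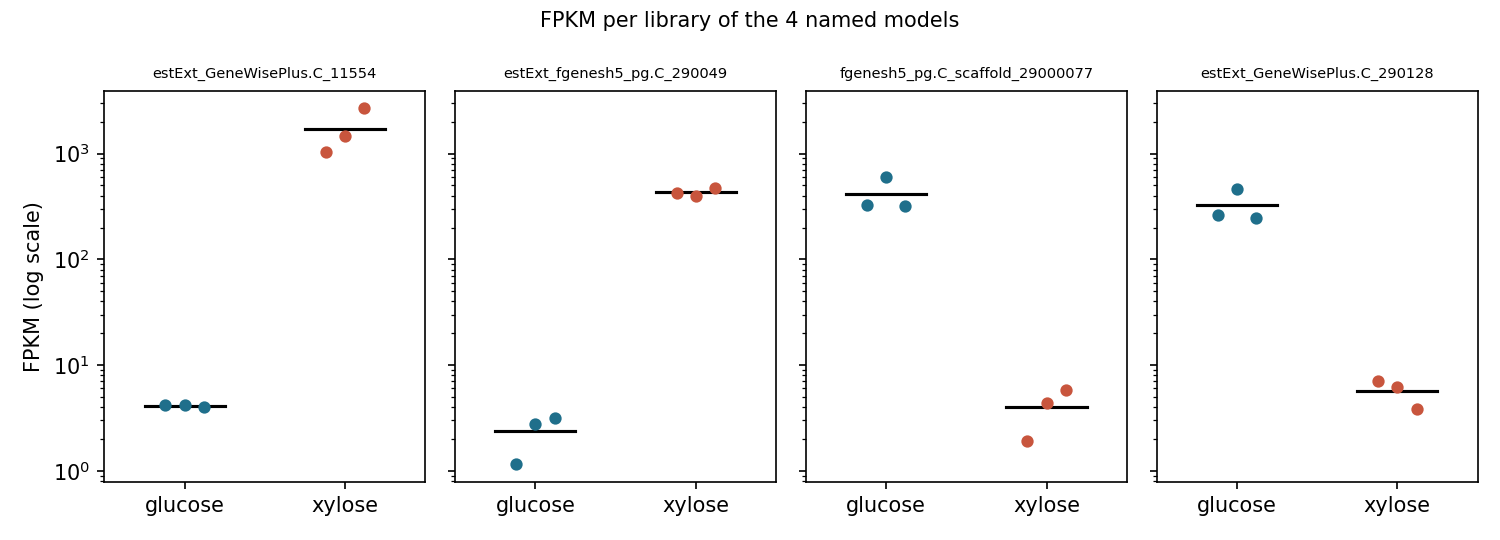
FPKM (vertical axis, log scale) of the 2 models with the largest rise and the 2 with the largest fall, with 1 point per library and a bar at the mean of 3 libraries. The groups are apart by 417-fold and 183-fold in the rising models and by 104-fold and 56.9-fold in the falling ones, as ratios of mean FPKM.

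Some scaffolds differed from the other models under 1 form of the test and not under another. Models of scaffold 7 rose less, with a median log2 fold change of 0.45 against 1.10 over all tested models, and 184 of its 396 models were higher and 117 lower. Models of scaffold 33 rose more, with a median of 1.86, and 28 of its 30 models were higher and 0 lower. Scaffolds 27, 29 and 30 rose less, with medians of 0.59, 0.67 and 0.40. Among 39 scaffolds with at least 20 tested models, these 5 passed limma's camera test with a preset correlation of 0.01, with adjusted p = 0.000106 for scaffold 7, 0.0117 for scaffolds 27, 30 and 33, and 0.0321 for scaffold 29. None held with an estimated correlation, where camera gave an adjusted p = 0.959 for each of them and 1 of 39 scaffolds had an unadjusted p under 0.05. With the median of ratios scaffold 7 (adjusted p = 0.000501) and scaffold 33 (adjusted p = 0.000799) stayed past the threshold and scaffolds 27, 29 and 30 did not (adjusted p = 0.097 each). That scaling turned the medians of scaffolds 7, 27, 29 and 30 to -0.59, -0.57, -0.25 and -0.51, while scaffold 33 stayed positive at 1.16. The call of scaffold 29 was also lost without xylose replicate 1 (adjusted p = 0.0667).

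**Figure D4:**
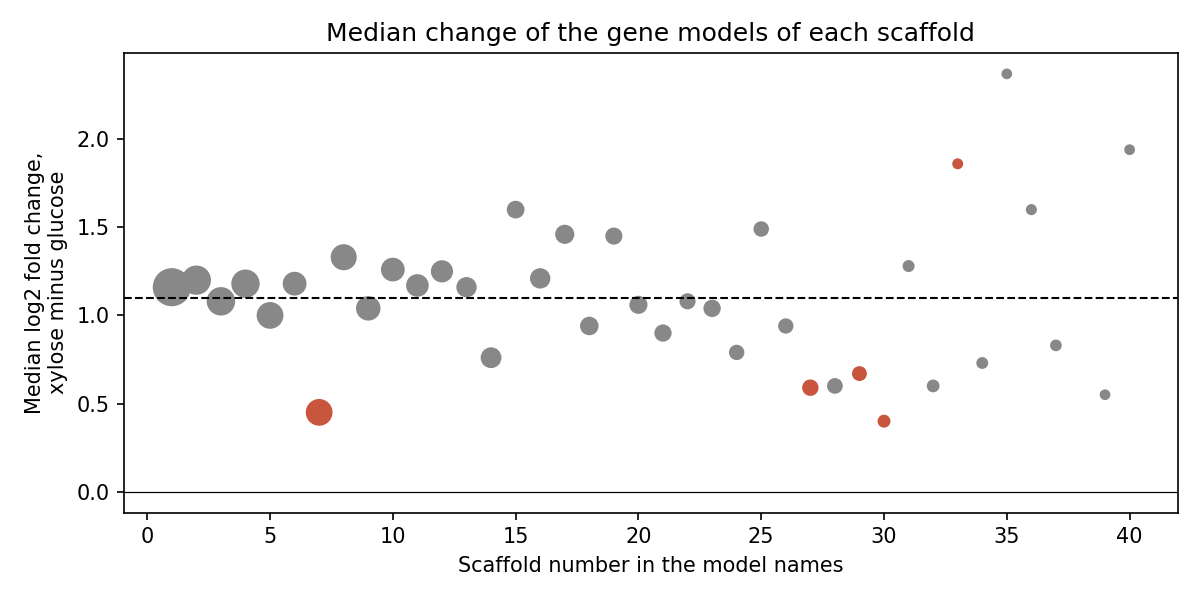
Median log2 fold change, xylose minus glucose (vertical axis), of the tested models of each scaffold (horizontal axis, scaffold number in the model names), with point area growing with the number of models and red for an adjusted p under 0.05 in camera with a preset correlation. No scaffold passed with an estimated correlation. The dashed line marks the median of all tested models, 1.10, and scaffold 7 lies at 0.45, which became -0.59 with the median of ratios.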

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

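The split between higher and lower calls was set by the scaling, and the scaffold calls by the correlation and the scaling. Higher calls fell from 5035 to 2980 with the median of ratios and 2551 with quantile normalization, while lower calls rose from 1095 to 2721 and 2627, and to 1737 when scaled on the reads outside the 100 most abundant models. The cause is in the construction of these scalings, which take out some or all of the shift. The median log2 fold change of 1.10 moved to 0.101, 0.005 and 0.673 under these 3 scalings, and to 0.655 with a pseudocount of 5. That pseudocount also left 3061 of 4702 models past 2-fold, because it shrinks low models. The lowest correlation within a group ran from 0.959 to 0.977 over the libraries left out. The 5 scaffold calls became 0 with an estimated correlation and 3 with the median of ratios (scaffolds 7, 33 and 35), and 4 to 5 when a library was left out, with scaffold 29 lost without xylose replicate 1. Limma's treat against a 1.5-fold change, a stricter test by construction, called 571 lower models. The other settings tried kept the counts of higher, lower and 2-fold models within 1.5 times, and the 4 named models kept their direction and passed the threshold under all 18 settings run on each. Voom on recovered reads, added after the table was seen, gave 4923 higher and 1057 lower, with 5958 of the calls shared with the main test. The replicate block gave 5034 higher and 1067 lower. The labels do not say that equal numbers share a culture or day, and the deviations of equal numbers correlated at 0.001, -0.072 and 0.073, and not every library correlated best with its own number, so the numbers were not taken as pairs. Reads limit models near 1 FPKM, where 1 read is a large step. Gene list tests, whose lists could not be filled, and the edgeR quasi-likelihood test were not run.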

Other observations

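The tests on neighbours, on strong falls by scaffold, on uniform background and on numbers of most abundant models other than 100 were chosen after the data were seen. Log2 fold changes of neighbours along scaffolds were compared within 4 series of gene models. Among 1616 tested models of one prediction series (fgenesh5_pg), ordered within each scaffold by the number in their names, the log2 fold changes of adjacent models correlated at r = 0.554 over 302 pairs. The correlation was 0.37 at 2 models apart, 0.311 at 3 and 0.249 at 5, and it was 0.042 at 10, inside the 95% range of shuffled orders (-0.08 to 0.178). At 50 apart it was -0.167, below that range there (-0.105 to 0.161), where the one-sided test for a positive correlation does not call it. At 1, 2 and 3 apart no shuffle within scaffolds reached the observed value (permutation p = 0.001, the smallest that 1000 shuffles can give, adjusted p = 0.0043 over 26 relations). The series were not tested against each other. In the estExt_fgenesh5_pg series adjacent models correlated at 0.34 (adjusted p = 0.0058) and models 10 apart at -0.012. In the estExt_GeneWisePlus series adjacent models did not pass (r = 0.271, 48 pairs, adjusted p = 0.088), while models 3 apart (r = 0.348, adjusted p = 0.0078) and 10 apart (r = 0.269, adjusted p = 0.039) did, and models 50 apart did not (r = 0.002, adjusted p = 0.74). Names starting with gw1 and with e_gw1 were merged into 1 order, keeping 1 model wherever a scaffold and number were shared. This merged series, the largest with 2487 models, did not pass at 1 apart (r = 0.064, adjusted p = 0.74). Nor did it pass at 3, 10 or 50 apart (r = 0.099, 0.082 and 0.04). The 2 kinds of name were not tested separately. Its pairs need not be neighbours, so that outcome cannot tell whether neighbours change together. The order along the scaffold is assumed in the other series too. These are correlations across genes, which are not independent replicates. Strong falls were also counted by scaffold. Of the 12 models that fell by at least 4 log2 units, 3 lay on scaffold 29, which holds 89 of the 7766 tested models (one-sided Fisher's exact test, p = 0.000297, adjusted p = 0.0116 over 39 scaffolds). That test was chosen after the named models were seen to share the scaffold, and the count rests on 3 models. Fisher's test also takes models as independent, while neighbours changed together in some series, so its p-values here and below can be too small. With the median of ratios, 3 of 45 such models lay on scaffold 29 and the call was lost (adjusted p = 0.19), while scaffold 32 passed with 4 (adjusted p = 0.0105). For strong changes in either direction no scaffold stood out after adjustment (lowest adjusted p = 0.395).

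A hypothesis for the neighbour pattern in the fgenesh5_pg series is that groups of adjacent genes are switched together by carbon source. Reads shared between adjacent models would act on direct neighbours alone, but models 3 apart still correlated at 0.311, above every shuffled order (highest 0.219). Similar abundance of neighbours was also not enough, since adjacent models correlated at 0.486 after the trend of fold change with mean level was removed (highest shuffled value 0.192). The numbers in the names are assumed to follow the order on the scaffold, which the names do not state. Without gene names, what these groups encode stays open.

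The second pattern is that the median tested model was higher in xylose while the median model above 500 FPKM was lower, on FPKM as deposited. The reads left by the 100 most abundant glucose models predict a shift of 0.53 log2 units (0.42 to 0.65 over 9 library pairings), while the other models shifted by 1.11 (0.83 to 1.44), and the prediction fell short by more than 0.2 in each pairing. That outcome rests on the number of models chosen. The prediction was 0.24 for the 10 most abundant models and 0.78 for 300, again short in all 9 pairings, but for 1000 it was 1.29 against 1.27 observed, within 0.2 in all 9, and for 3000 it was 1.98 against 1.57. A few dominant models are thus too few to account for the shift. Fewer reads taken by about 1000 models stays open, and the limit set for 100 models was too narrow to exclude it. The predictions hold no pseudocount, while the observed shifts are on the log2(FPKM + 1) scale, which understates low models. Over all tested models the median shift was 1.10 with a pseudocount of 1 and 1.31 with 0.1. The match at 1000 models and the excess at 3000 can therefore come from this difference of scale. The prediction rises with the number of models and is taken from the reads of the other models, whose median is the value observed. A match at some number thus partly restates the observation and is no evidence for that number. Uniform background reads, as from genomic DNA, would add the same FPKM to every model, but models at 1 to 2 FPKM in glucose gained at least 6.1 times as much as those at 0.05 to 0.2 FPKM in each xylose library (models of at least 1000 nt). That test replaced 2 earlier ones after their outcomes were seen. The first counted models at 0 in xylose among those at 0 in glucose, and was dropped because models to which no reads can be mapped would be at 0 too. The next counted models whose level in xylose lay under 0.5 of the median gain, against the number expected from a uniform gain. It gave 1.9, 0.8 and 0.3 times the expected number in xylose replicates 1, 2 and 3, a mixed outcome. The excess in replicate 1 goes against a uniform gain in that library alone. The expected number left out the models' own expression and is an upper limit, so the ratios under 1 cannot decide. The last test was therefore picked knowing these outcomes, and it excludes background only as the whole cause. Gene length is argued against too, since the lowest median over 4 length groups of equal size was 1.04. What stays open is whether transcript amounts per cell rose or the abundant transcripts fell, which FPKM cannot separate without an outside standard. No biological explanation of the shift was tested.

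Among the 10 splits of the 6 libraries into 3 and 3, only 1, the real one, reached 5035 higher, 1095 lower and 4702 models changed at least 2-fold. The highest count in any other split was 0, by the same limma test, and 10 splits are too few for a share under 0.05. Every other split mixes the carbon sources, so their difference enters the spread within its groups. Counts of 0 there therefore do not measure false calls.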
